A study of Mus musculus with 6 samples.

How the data were processed

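RNA was sequenced from mammary epithelial organoids of FVB mice on lactation day 1. Organoids are fragments of the mammary epithelium, freed from the second and the third mammary glands with collagenase and pronase and enriched by short centrifugation, per the labels. The genotypes were wild type (3 mice) and a conditional knockout of Nmi (3 mice), with 1 library per mouse. Each mouse carried its own number in the labels and was treated as a separate animal. The numbers do not show whether mice of both genotypes shared a litter or a day of collection, so no pairing was used.

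The values were FPKM (fragment numbers scaled to the length of the gene and to the total of the library), as the authors deposited them in 1 table of 17739 gene symbols for the 6 libraries. Per the submitters' processing notes, the tools were FastQC, TopHat, SAMtools and Cufflinks, and the genome builds were named mm10 and GRCm38. Tool versions, parameters, strand settings and the gene annotation are not given in the sources used here. FPKM divides by each library's own total, so genes that take a large share of a library lower the FPKM of the others. Gapdh, which is abundant in nearly every cell, was listed between 0 and 0.0769 FPKM in the 6 libraries, so a low or zero entry can be a failed estimate and was not read as absence.

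Read counts cannot be had from these values, and the absolute depth of the libraries is unknown. The relative depth was estimated from 456 genes with FPKM between 0.001 and 0.1, as the most frequent log2 ratio of a library to wild-type replicate 1. It ran from 0.975 to 1.13 times that of wild-type replicate 1. Only small ratios were searched, so a large difference in depth could not have been found. No counting interval or detection floor was computed, and precision was taken from the spread between mice.

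Genes with FPKM of at least 1 in at least 3 libraries were tested, which left 9767 genes. Values were transformed to log2(FPKM + 1), so fold changes are on the scale with a pseudocount of 1 and understate the change of low genes. The genotypes were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All limma tests were two-sided. The 3 against 3 design allows an exact permutation p no lower than 0.1 for a single gene.

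Gene lists were fixed before the data were examined: 28 lists with 681 genes, of which 651 were in the table and 460 were tested. They cover milk proteins, milk lipid and cholesterol synthesis, prolactin and STAT5 signalling, Wnt targets, Wnt ligands with receptors and regulators, interferon-stimulated genes, NF-kB targets, TGF-beta targets, Notch and Hedgehog targets, cell cycle, epithelial-mesenchymal transition, the unfolded protein response, involution, dissociation stress, luminal, hormone-sensing and basal epithelial markers, 9 other cell types, the mitochondrial respiratory chain and ribosomal proteins. A gene can sit in several lists, as 23 genes did. The 24 lists with at least 5 tested genes were tested with camera from limma, which compares a list with all other genes, at a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment was made over the lists. Camera was repeated with the correlation estimated from the data, and fry, a rotation test of whether a list moves one way on balance, was run as a further alternative.

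The genes named in the text were chosen by a rule fixed before the data were examined. It took Nmi, then 10 genes higher and 10 lower in the knockout among those past the adjusted threshold with non-overlapping groups, or, where too few passed, those with the smallest unadjusted p and non-overlapping groups. Predicted gene models and genes with a near-identical copy were skipped there. Copies were found with BLAST 2.17.0 as transcripts of other genes at 95% identity or more over at least 50% of the longest transcript. The rule also took 4 members with the smallest p in the list's direction from each list called by camera. It took 3 members with the smallest p from the milk protein, STAT5, Wnt, interferon, cell cycle, luminal, hormone-sensing and basal lists. From the lists of other cell types it took the 2 members with the highest FPKM. This gave 97 genes. After the data were seen, fold changes were printed only for the 41 genes from the first parts of the rule or with an unadjusted p under 0.1, and the other 56 were given as levels where the text names them. Coordinates were taken from GENCODE mouse release 21 on GRCm38, the build named by the submitters, which held 97.2% of the tested symbols.

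The tests were checked on simulated data for the same comparison and the same 9767 genes with 200 genes changed. With noise at the measured spread, 30% of changes of 1 on the log2 scale and 80% of changes of 2 were recovered, with 8 false calls. With effects added to the measured values themselves, 37% and 91% were recovered, with 1 false call.

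The alternatives, fixed beforehand, were pseudocounts of 0.1 and 5, no filter and an FPKM minimum of 5, rescaling with trimmed-mean (TMM-type) factors, quantile normalization, rescaling to the FPKM sum outside the milk protein list, library quality weights, a robust prior, no intensity trend, and each library left out in turn. After the data were seen, a fit without the libraries at both ends of the first principal component and a fit with the mean of the milk protein list as a covariate were added. The 10 splits of the 6 libraries into 3 and 3 were all fitted. Tables were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.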

Results

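Gene expression was measured in mammary epithelial organoids from 6 mice on lactation day 1, 3 wild type and 3 with a conditional knockout of Nmi. Nmi encodes an interferon-inducible protein that binds Myc and STAT proteins. Per the series' description, the comparison asks how loss of Nmi contributed to excess proliferation of the mammary epithelium in puberty and lactation. The day was chosen because Nmi protein is then at its highest in normal mammary epithelium.

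Milk transcripts made up most of 5 of the 6 libraries. The 20 genes of the milk protein list held 47.8%, 60.9% and 69.7% of the FPKM sum in wild-type replicates 1, 2 and 3, and 66.4%, 63.2% and 75.5% in knockout replicates 1, 2 and 3. Csn2, which encodes beta-casein, ranged from 54112 FPKM in wild-type replicate 1 to 142436 FPKM in knockout replicate 3. Actb, which encodes beta-actin, ranged the other way, from 1495 FPKM in wild-type replicate 1 to 481 FPKM in knockout replicate 3. The FPKM sums ran from 379478 to 509453, and between 9084 and 10116 genes had an FPKM of at least 1. The first principal component held 73.8% of the variance and placed wild-type replicate 1 at -0.61 and knockout replicate 3 at 0.72, with the other 4 libraries of both genotypes between -0.21 and 0.16. Pairs of libraries within a genotype correlated across genes no better (mean Pearson r 0.956, 6 pairs) than pairs between genotypes (0.956, 9 pairs). Genotype accounted for 21.7% of the variance, the fifth highest of the 10 possible splits of the libraries into 3 and 3, of which the highest took 51.3%.

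**Figure D1:**
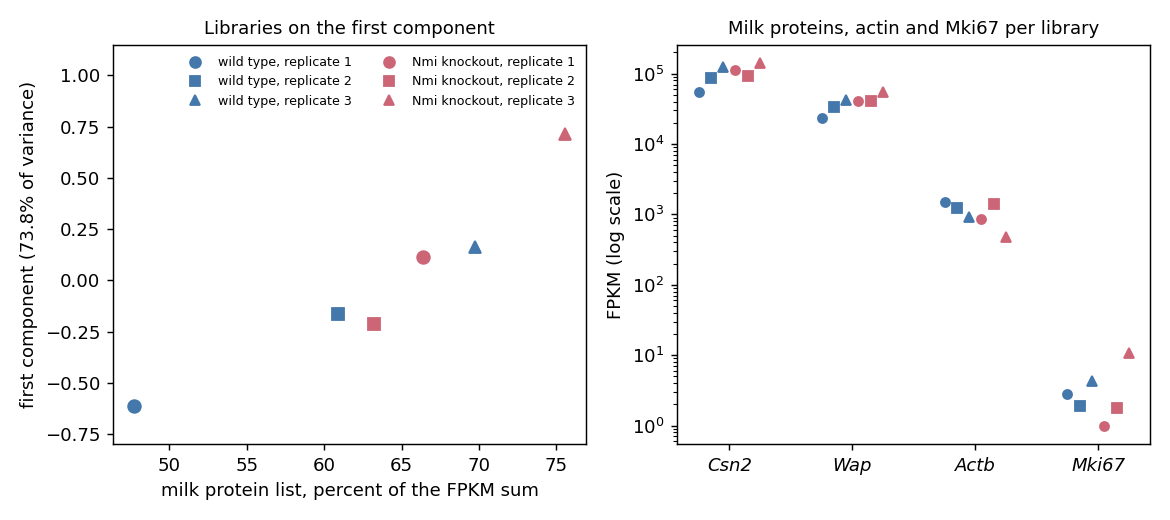
Left, score of each library on the first principal component of log2(FPKM + 1), as deposited, against the share of the milk protein list in its FPKM sum; right, FPKM of Csn2, Wap, Actb and Mki67 in each library on a log axis. Wild-type replicate 1 (47.8% milk transcripts) and knockout replicate 3 (75.5%) lay at the ends of the component, and the other 4 libraries of both genotypes lay between them.

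Nmi itself was lower in the 3 knockout libraries than in the 3 wild-type libraries. The gene lies on chromosome 2 of GRCm38 at 51948487 to 51973494, on the minus strand, with 6 annotated transcripts. Its FPKM was 4.60, 2.82 and 2.32 in wild-type replicates 1, 2 and 3 and 0.188, 0.547 and 0.564 in knockout replicates 1, 2 and 3. The means were 3.25 ± 1.19 FPKM and 0.433 ± 0.213 FPKM (SD, n = 3 each), so the knockout held 13.3% of the wild-type level. The log2 fold change was -1.54 (SE 0.23, 95% confidence interval -2.06 to -1.03). Nmi had the smallest p of all 9767 genes tested, unadjusted p = 3.81e-05, and an adjusted p of 0.372 with limma and Benjamini-Hochberg adjustment, which did not pass the threshold. The exact permutation test of Nmi alone gave p = 0.1, the smallest value that 3 against 3 mice allow. The labels do not say which exons were removed, so the remaining FPKM was not divided between deleted and intact parts of the gene.

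No single gene, Nmi included, passed the adjusted threshold between the genotypes. With limma and Benjamini-Hochberg adjustment, 0 genes were higher and 0 were lower in the knockout at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 130 genes, 18 higher and 112 lower, where 488 would be expected by chance. That number was 25 without wild-type replicate 1, 632 without wild-type replicate 3, 1187 without knockout replicate 2 and 59 without knockout replicate 3. The groups did not overlap for 450 genes, 76 higher and 374 lower, which is 4.61% of those tested against the 10% that chance gives for 3 against 3. Most genes had negative fold changes. The median log2 fold change of all genes was -0.21 as deposited and 0.01 after trimmed-mean rescaling. After rescaling, 55.5% of the genes at an unadjusted p under 0.05 were higher, against 13.8% as deposited. The share was 48.6% after quantile normalization and 44.2% after scaling to the sum outside the milk protein list. Fold changes below are as deposited, and values relative to the median of all genes are given where directions depend on them. The median half-width of the 95% confidence interval of a gene was 0.57 on the log2 scale, before any adjustment for the number of genes. In the simulation on the measured values, 200 genes were changed together, and 37% of changes of 1 and 91% of changes of 2 passed the adjusted threshold. Most changes of 1 or less were thus not detectable here. With fewer changed genes the adjustment demands a smaller unadjusted p, so these shares cannot be carried over to a lone changed gene. Nmi itself, at -1.54, did not pass (adjusted p = 0.372, limma with Benjamini-Hochberg adjustment). The absence of calls therefore does not exclude lone changes of 2.

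The 9 genes besides Nmi that were lower in all knockout libraries with the smallest unadjusted p did not pass the adjusted threshold (each adjusted p = 0.768, limma with Benjamini-Hochberg adjustment). Cdk5rap1, a mitochondrial tRNA-modifying enzyme, had 2.49 ± 0.699 FPKM in wild type and 0.745 ± 0.308 FPKM in the knockout (SD, n = 3 each), a log2 fold change of -0.995 (SE 0.22). The iron exporter Slc40a1 (ferroportin) had 3.29 ± 2.07 FPKM and 0.943 ± 0.687 FPKM. The Polycomb chromobox genes Cbx6 and Cbx7 had log2 fold changes of -0.94 (SE 0.29) and -0.80 (SE 0.25), and the annotated end of Cbx7 overlaps its neighbour Apobec3. Psat1, an enzyme of serine synthesis, had 24.1 ± 10.7 FPKM in wild type and 11.3 ± 1.46 FPKM in the knockout. Wfdc12, a small secreted protein, had a log2 fold change of -1.47 (SE 0.45). The others were the transcription factor gene Glis3 (-1.02, SE 0.36), the long non-coding RNA Lncppara (-0.99, SE 0.27) and Lurap1 (-0.54, SE 0.19). Relative to the median of all genes, these 9 genes lay between -1.26 (Wfdc12) and -0.33 (Lurap1). Without wild-type replicate 1 the fold changes were smaller for Glis3 (-0.57), Slc40a1 (-0.73, against -1.10 with all libraries) and Psat1 (-0.62, against -0.95), and without knockout replicate 3 for Wfdc12 (-0.85).

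The 10 genes higher in all knockout libraries with the smallest unadjusted p did not pass either (each adjusted p = 0.768), and 1 predicted gene model was skipped among them. Fdx1, which passes electrons to mitochondrial cytochrome P450 enzymes, had 9.60 ± 5.49 FPKM in wild type and 21.3 ± 5.20 FPKM in the knockout (SD, n = 3 each), a log2 fold change of 1.16 (SE 0.35). The growth factor gene Pdgfd had 0.770 ± 0.282 FPKM and 2.39 ± 1.42 FPKM, a log2 fold change of 0.88 (SE 0.27). Casp4, an inflammatory caspase, had 7.69 ± 2.02 FPKM and 12.3 ± 1.88 FPKM. Tnfaip8 had 5.75 ± 0.761 FPKM and 8.96 ± 0.800 FPKM. Shank2, a scaffold protein (log2 fold change 0.82, SE 0.33), and Tbc1d4, a regulator of insulin-stimulated glucose uptake (0.67, SE 0.28), were also among them. The remaining genes were Fam110a (0.75, SE 0.29), the monocarboxylate transporter gene Slc16a12 (0.64, SE 0.25), the phosphatase gene Ppm1j (0.54, SE 0.23) and the sulfotransferase gene Sult1a1 (0.50, SE 0.20). Without wild-type replicate 1 the log2 fold change was 0.40 for Shank2 and 0.485 for Fam110a, and without knockout replicate 3 it was 0.55 for Pdgfd and 0.43 for Tbc1d4.

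**Figure D2:**
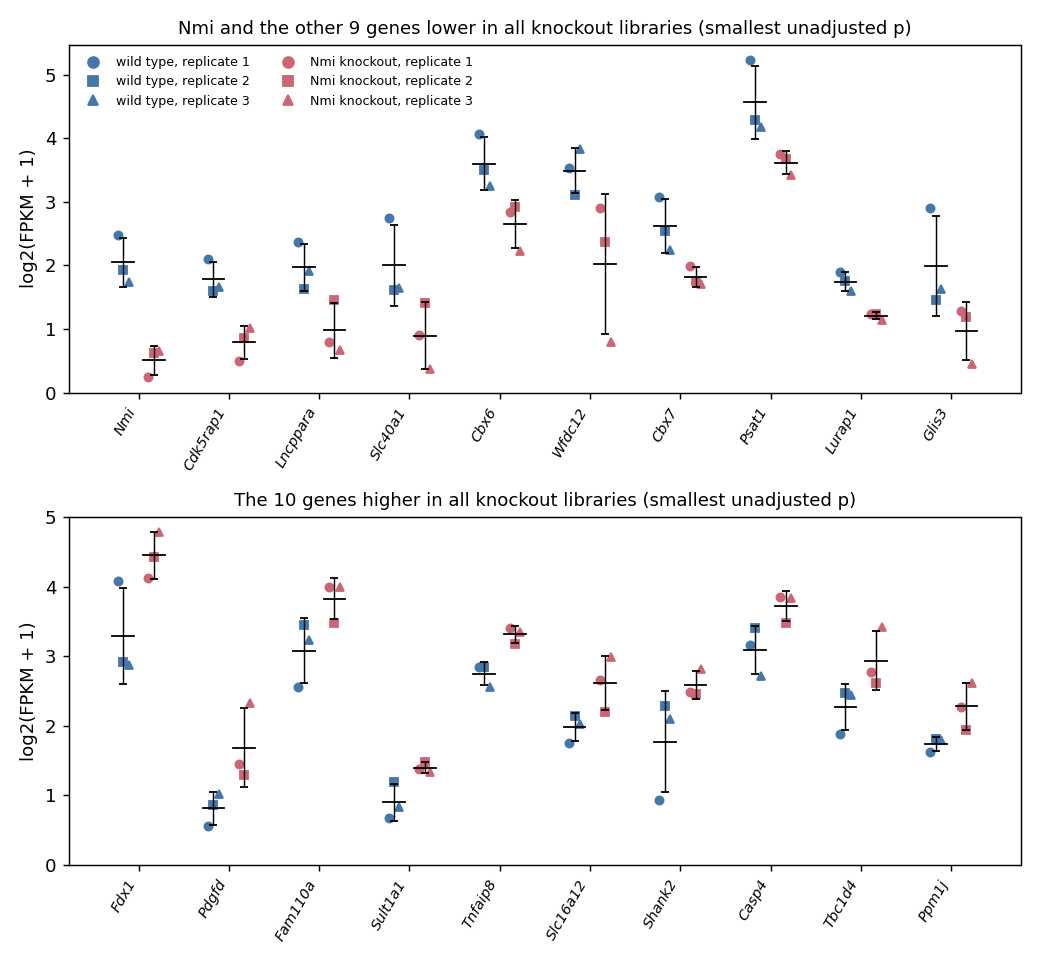
log2(FPKM + 1) of Nmi and 9 other genes lower in all 3 knockout libraries (top) and 10 genes higher in all 3 (bottom), selected by unadjusted p; each point is 1 library, and black lines give the mean and SD of the log2 values in each genotype (n = 3). Groups do not overlap by selection, and 0 of these genes passed the adjusted threshold; Nmi had a log2 fold change of -1.54.

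Camera at the preset correlation called 10 gene lists higher, milk synthesis among them, and 1 lower, the luminal alveolar and progenitor markers, relative to all other genes. These calls did not hold when camera used an estimated correlation: 0 lists were called (smallest adjusted p = 0.164, 5 lists at an unadjusted p under 0.05). With fry 0 were called (smallest adjusted p = 0.883, 0 at an unadjusted p under 0.05). Fry puts a different question, whether a list moves from 0. A list can thus lie above the other genes without a call by fry. In every list tested, 0 members passed over all genes and 0 passed when adjusted over the list alone. Counts of members below are relative to the median of all genes. For Wnt targets, basal markers and ribosomal protein genes, none of them called, the test leaned to the higher side although most members lay under that median.

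Of the 35 genes of milk lipid and cholesterol synthesis, 35 lay above the median of all genes (camera adjusted p = 3.78e-29, and adjusted p = 0.164 with an estimated correlation). Lpin1, an enzyme of triglyceride synthesis, had 6.57 ± 4.59 FPKM in wild type and 18.3 ± 14.4 FPKM in the knockout (SD, n = 3 each). The fatty acid elongase gene Elovl6 had 4.41 ± 2.42 FPKM and 7.05 ± 2.43 FPKM, and Cyp51, a cholesterol synthesis enzyme, had 7.397 ± 0.782 FPKM and 10.97 ± 3.11 FPKM. Idi1, of the mevalonate pathway, had 15.4 ± 2.44 FPKM and 21.7 ± 3.94 FPKM. The log2 fold change of Lpin1 was 1.29, but 0.67 without wild-type replicate 1 and 0.71 without knockout replicate 3. That of Elovl6 was 0.63, but 0.31 and 0.40 without these libraries and 0.96 without wild-type replicate 3. Of the 20 milk protein genes, 18 lay above the median (camera adjusted p = 1.71e-11, and adjusted p = 0.325 with an estimated correlation). The whey acidic protein gene Wap had 33248 ± 9580 FPKM in wild type and 45677 ± 7900 FPKM in the knockout. The milk fat globule gene Btn1a1 had 293 ± 126 FPKM and 417 ± 106 FPKM, the lipase gene Cel 249 ± 139 FPKM and 404 ± 224 FPKM, and the casein gene Csn1s2b 635 ± 572 FPKM and 957 ± 643 FPKM. The wild-type mean of Csn1s2b was 309 FPKM without wild-type replicate 3. Its knockout mean was 597 FPKM without knockout replicate 3, under the wild-type mean of 635 FPKM with every wild-type library kept. Plin2, which coats lipid droplets, went against the list, with 735 ± 245 FPKM in wild type and 462 ± 215 FPKM in the knockout. Without the libraries at both ends of the first component, both lists turned to the lower side and neither was called (adjusted p = 0.814 for lipid synthesis and 0.199 for milk proteins). With the milk covariate, which is built from the milk protein list, that list was not called (0.372).

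Of the 16 tested markers of luminal alveolar and progenitor cells, 14 lay below the median of all genes (camera adjusted p = 0.00168, and adjusted p = 0.574 with an estimated correlation). Lypd3 had 44.0 ± 9.66 FPKM in wild type and 22.4 ± 11.98 FPKM in the knockout (SD, n = 3 each), a log2 fold change of -1.09 (SE 0.41), which was -0.58 without knockout replicate 3. The keratin gene Krt7 had 109 ± 93.8 FPKM and 35.9 ± 39.1 FPKM, the receptor gene Kit 22.0 ± 17.6 FPKM and 9.004 ± 4.78 FPKM, and Cd14 446 ± 62.7 FPKM and 276 ± 94.9 FPKM. Without wild-type replicate 1 the log2 fold change of Krt7 was -1.298 instead of -1.97, and that of Kit -0.50 instead of -1.09. Without knockout replicate 3 it was -0.93 for Krt7, -0.59 for Kit and -0.44 instead of -0.75 for Cd14. The knockout mean of Krt7 was 14.1 FPKM without knockout replicate 2, which widens the difference. The call ended without both end libraries (adjusted p = 0.0502) and with library quality weights (0.833). Neither hormone-sensing luminal markers (7 of 10 above the median, camera adjusted p = 0.189) nor basal markers (9 of 22 above it, 0.911) were called. Among the former, Ly6a had 52.1 ± 30.6 FPKM in wild type and 30.4 ± 13.5 FPKM in the knockout, Cited1 1.29 ± 1.05 FPKM and 0.764 ± 0.250 FPKM, and the estrogen receptor gene Esr1 0.921 ± 0.271 FPKM and 1.30 ± 0.789 FPKM. Without wild-type replicate 1 the wild-type means of Ly6a and Cited1 were 34.7 and 0.707 FPKM, and without knockout replicate 3 the knockout mean of Esr1 was 0.868 FPKM; for Cited1 and Esr1 this turned the order of the groups. Among basal markers, Trp63, which encodes p63, had 5.15 ± 3.53 FPKM and 2.29 ± 0.501 FPKM, Itgb4 20.3 ± 8.02 FPKM and 13.8 ± 10.003 FPKM, and Krt14 110.1 ± 42.4 FPKM and 85.6 ± 47.5 FPKM. The log2 fold change of Trp63 was -0.77, but -0.33 without wild-type replicate 1, and the knockout mean of Itgb4 was 8.63 FPKM without knockout replicate 2.

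**Figure D3:**
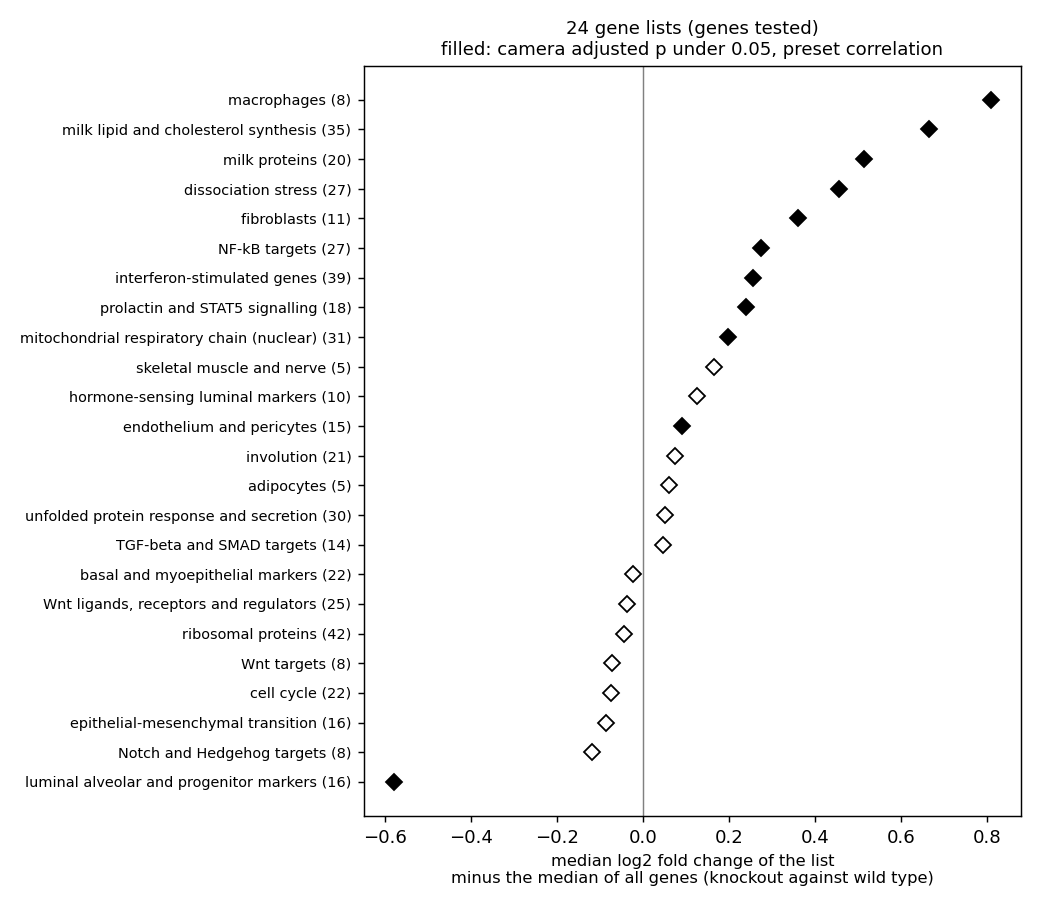
Median log2 fold change (knockout against wild type) of each of 24 gene lists minus the median of all genes, with the number of tested genes in parentheses; filled symbols mark camera adjusted p under 0.05 at the preset correlation. Macrophage genes lay highest, at 0.81, and luminal alveolar and progenitor markers lowest, at -0.58; 0 lists were called with an estimated correlation.

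The prolactin and STAT5 list, the pathway that switches on milk genes, had 13 of 18 genes above the median of all genes (camera adjusted p = 0.00606, and adjusted p = 0.229 with an estimated correlation). Its median log2 fold change was 0.03 and its mean -0.06, both above the median of all genes (-0.21). The call is relative to all other genes, so it does not mean that the list rose above 0. Stat5a had 11.7 ± 5.01 FPKM in wild type and 18.1 ± 6.01 FPKM in the knockout (SD, n = 3 each), Socs3 18.7 ± 3.64 FPKM and 28.6 ± 12.2 FPKM, Ghr 6.95 ± 0.617 FPKM and 8.09 ± 1.73 FPKM, and Elf5 168 ± 7.77 FPKM and 195 ± 48.7 FPKM. The junction genes Cldn3 (347 ± 149 and 205 ± 120 FPKM) and Cdh1 (176 ± 66.8 and 112 ± 63.9 FPKM) had lower means in the knockout. The call ended after trimmed-mean rescaling (adjusted p = 0.0668), after quantile normalization (0.06) and without wild-type replicate 1 (0.116). It also ended without a filter (0.407), with library quality weights (0.180), without both end libraries (0.577) and with the milk covariate (0.199).

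Cell cycle genes, which bear on proliferation, were not called (6 of 22 above the median of all genes, camera adjusted p = 0.104, and adjusted p = 0.822 with an estimated correlation). Cenpa, a centromeric histone, had 2.02 ± 0.778 FPKM in wild type and 0.965 ± 0.0492 FPKM in the knockout (SD, n = 3 each), a log2 fold change of -0.59 (SE 0.21), and -0.39 without wild-type replicate 1. Cdk1 had 1.48 ± 0.521 FPKM and 0.637 ± 0.390 FPKM, and Ube2c 5.65 ± 3.26 FPKM and 2.39 ± 2.14 FPKM. Knockout replicate 3 stood apart from the other knockout libraries. It had 10.7 FPKM of the proliferation marker Mki67, a gene outside the naming rule, against 0.983 and 1.80 FPKM in knockout replicates 1 and 2. Wild type had 1.896 to 4.32 FPKM. The list as a whole did not exceed wild type in this way. Its mean log2 level, centred on the 6 libraries, was 0.38 in knockout replicate 3 and -0.58 and -0.27 in knockout replicates 1 and 2. In wild-type replicates 1, 2 and 3 it was 0.37, -0.18 and 0.29. Without knockout replicate 3 the list was called lower (adjusted p = 9.60e-32, and 0.347 with an estimated correlation). It was also called lower without wild-type replicate 1 (0.0128, and 0.797 with an estimated correlation) or 2 (1.11e-05, and 0.510). The same held without both end libraries (1.15e-35, and 0.889 with an estimated correlation), with the milk covariate (1.95e-07, and 0.522), with library quality weights (0.00694, and 0.762) and without a filter on 50 genes (0.00548, and 0.872). The list turned to the higher side, not called, without wild-type replicate 3 or knockout replicate 1 or 2.

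Neither Wnt list was called. Of 8 tested Wnt targets, 3 lay above the median of all genes (camera adjusted p = 0.404), and of 25 ligands, receptors and regulators, 12 did (0.919). Among the targets, Cd44 had 12.1 ± 6.30 FPKM in wild type and 7.87 ± 5.07 FPKM in the knockout, Myc 43.2 ± 15.9 FPKM and 31.0 ± 15.9 FPKM, and Ccnd1, which encodes cyclin D1, 5.10 ± 1.17 FPKM and 7.10 ± 2.30 FPKM (SD, n = 3 each). Among the ligands and regulators, Wnt5b had 15.2 ± 5.87 FPKM and 8.23 ± 5.98 FPKM, a log2 fold change of -0.997 (SE 0.47) and -0.42 without knockout replicate 3, Sfrp2 2.35 ± 1.11 FPKM and 3.60 ± 0.674 FPKM, and Rspo1 1.78 ± 0.939 FPKM and 0.978 ± 0.869 FPKM. Without knockout replicate 2 the knockout means of Wnt5b, Cd44 and Rspo1 were 5.13, 4.94 and 0.494 FPKM. The log2 fold change of Sfrp2 was 0.50, but 0.31 without wild-type replicate 1 and 0.75 without wild-type replicate 3.

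Interferon-stimulated genes, a class to which Nmi belongs, lay above the median of all genes for 34 of 39 members (camera adjusted p = 1.36e-08, and adjusted p = 0.567 with an estimated correlation). The median log2 fold change was 0.05 as deposited. The guanylate-binding protein genes Gbp6 and Gbp3 had 1.03 ± 0.561 and 4.07 ± 0.539 FPKM in wild type and 1.56 ± 0.501 and 5.92 ± 2.80 FPKM in the knockout (SD, n = 3 each). The nucleic acid sensor gene Zbp1 had 0.968 ± 0.123 FPKM and 1.32 ± 0.171 FPKM, and Ifi47 1.47 ± 0.453 FPKM and 2.02 ± 0.506 FPKM. Oasl1 went the other way, with 5.16 ± 3.14 FPKM and 3.18 ± 1.17 FPKM, and a wild-type mean of 3.39 FPKM without wild-type replicate 1. Without knockout replicate 3 the list was no longer called (adjusted p = 0.282). Of the 27 NF-kB targets, 23 lay above the median (camera adjusted p = 2.83e-08, and adjusted p = 0.164 with an estimated correlation). Tnfaip3, a feedback inhibitor of NF-kB, had 2.16 ± 0.283 FPKM and 3.46 ± 0.826 FPKM, a log2 fold change of 0.48 (SE 0.22). The NF-kB subunit gene Rel had 1.03 ± 0.504 FPKM and 2.06 ± 1.27 FPKM, Birc3 12.2 ± 1.99 FPKM and 16.4 ± 2.58 FPKM, and Tnfaip2 4.37 ± 0.781 FPKM and 6.83 ± 4.60 FPKM. The log2 fold change of Rel was 0.55, but 0.33 without wild-type replicate 1 and 0.23 without knockout replicate 3. The knockout mean of Tnfaip2 was 4.32 FPKM without knockout replicate 2, under the wild-type mean. The NF-kB call ended with library quality weights (adjusted p = 0.159).

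Genes that respond to tissue dissociation lay above the median of all genes for 24 of 27 members (camera adjusted p = 3.41e-12, and adjusted p = 0.229 with an estimated correlation). The immediate early genes Fos and Egr1 had 43.4 ± 21.4 FPKM and 10.2 ± 6.11 FPKM in wild type and 103 ± 76.7 FPKM and 21.9 ± 11.4 FPKM in the knockout (SD, n = 3 each). Fosb had 18.7 ± 14.97 FPKM and 35.6 ± 17.1 FPKM, and Zfp36 68.3 ± 5.51 FPKM and 127 ± 80.9 FPKM. Without knockout replicate 3 the log2 fold change was 0.56 instead of 1.12 for Fos, 0.70 instead of 1.08 for Egr1 and 0.23 instead of 0.71 for Zfp36. Without wild-type replicate 1 it was 0.63 for Fos, 0.65 for Egr1 and 0.45 instead of 1.07 for Fosb, which had 1.66 without wild-type replicate 2. Without both end libraries this list turned to the lower side and was not called (adjusted p = 0.275), as with library quality weights (0.948).

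**Figure D4:**
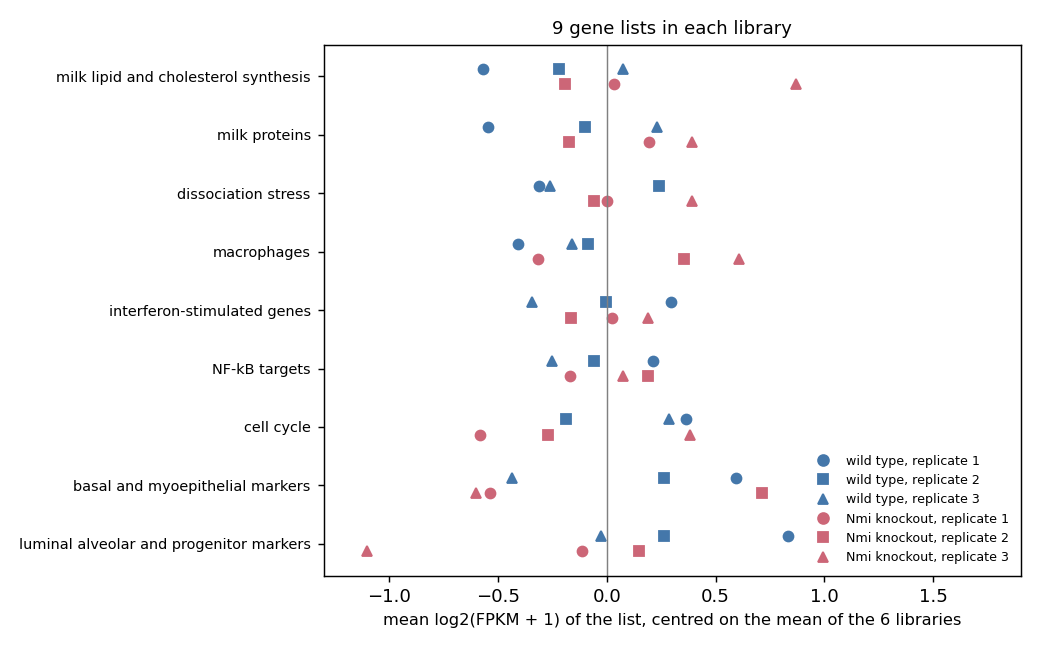
Mean log2(FPKM + 1) of the members of 9 gene lists in each library, centred on the mean of the 6 libraries; each point is 1 library, coloured by genotype. The genotypes overlap in every list shown; luminal alveolar and progenitor markers run from 0.83 in wild-type replicate 1 to -1.10 in knockout replicate 3.

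Markers of cell types other than epithelium were also measured. Of 8 tested macrophage genes, 7 lay above the median of all genes (camera adjusted p = 1.81e-09, and adjusted p = 0.164 with an estimated correlation). The antigen presentation genes Cd74, H2-Aa and H2-Ab1 had 20.2 ± 2.97, 4.04 ± 0.291 and 6.42 ± 1.02 FPKM in wild type and 36.9 ± 21.2, 8.16 ± 3.85 and 11.01 ± 5.91 FPKM in the knockout (SD, n = 3 each). The complement genes C1qa and C1qb had 1.45 ± 0.359 and 1.47 ± 0.622 FPKM in wild type and 3.21 ± 2.10 and 3.10 ± 1.73 FPKM in the knockout. Without knockout replicate 3 the log2 fold change was 0.47 instead of 0.77 for H2-Aa and 0.36 instead of 0.68 for C1qb. Without both end libraries the adjusted p for macrophage genes was 0.275, and with library quality weights the list turned to the lower side (0.686). Fibroblast genes (10 of 11 above the median) had a camera adjusted p of 4.25e-05, and 0.574 with an estimated correlation. Endothelial and pericyte genes (13 of 15 above the median) had a camera adjusted p of 0.0394, and 0.822 with an estimated correlation, although their median log2 fold change was -0.12 as deposited. Col1a1 had 7.76 ± 3.73 FPKM in wild type and 9.79 ± 3.85 FPKM in the knockout, Postn 43.4 ± 16.6 FPKM and 44.1 ± 30.5 FPKM, the endothelial gene Cldn5 42.6 ± 9.58 FPKM and 33.5 ± 12.2 FPKM, and Cdh5 29.9 ± 8.22 FPKM and 26.9 ± 10.5 FPKM. The order of the group means turned for Col1a1 and Postn without wild-type replicate 3, for Postn without knockout replicate 2 (26.9 FPKM in the knockout) and for Cdh5 without knockout replicate 3. The fibroblast call ended without wild-type replicate 3 (adjusted p = 0.276) or knockout replicate 2 (0.138), and the endothelial call without wild-type replicate 3 (0.852) or knockout replicate 1 (0.0637) or 2 (0.392). The endothelial call also ended at a pseudocount of 5 (0.0622), at an FPKM minimum of 5 (0.0618) and without a filter (0.219). With library quality weights the endothelial call ended (0.496) and the fibroblast list was called lower (0.0164).

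Adipocyte genes (4 of 5 above the median, camera adjusted p = 0.212) and genes of skeletal muscle and nerve (4 of 5, 0.248) were not called. Fabp4 had 461 ± 232 FPKM in wild type and 287 ± 143 FPKM in the knockout, Cidea 143 ± 59.2 FPKM and 187 ± 92.6 FPKM, and Sox10 105 ± 21.2 FPKM and 72.5 ± 26.2 FPKM (SD, n = 3 each). The order of the means of Cidea turned without knockout replicate 3. Cidea and Sox10 are also expressed by mammary epithelium, as is Sdc1 of the B and plasma cell list (23.6 ± 13.3 FPKM and 15.1 ± 5.05 FPKM). Of the lists with too few tested genes, T and NK cells had 0 genes, neutrophils and mast cells 1, B and plasma cells 2 and erythrocytes 4. The neutrophil gene S100a8 had 4.60 ± 2.96 FPKM in wild type and 4.85 ± 3.68 FPKM in the knockout, and the globin gene Hbb-b1 4.36 ± 1.40 FPKM and 6.76 ± 5.38 FPKM. Without knockout replicate 3 the knockout mean of Hbb-b1 was 3.66 FPKM, under the wild-type mean. The wild-type mean of S100a8 was 2.89 FPKM without wild-type replicate 1, and its order turned without wild-type replicate 2 or 3 or knockout replicate 1 (2.97 FPKM in the knockout).

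Of 31 nuclear genes of the mitochondrial respiratory chain, 29 lay above the median of all genes (camera adjusted p = 0.00256, and adjusted p = 0.822 with an estimated correlation), while their median log2 fold change was -0.01 as deposited. Ndufa1 had 49.98 ± 10.9 FPKM in wild type and 56.0 ± 3.36 FPKM in the knockout, and Cox5a 39.0 ± 7.16 FPKM and 41.8 ± 6.24 FPKM (SD, n = 3 each), and the order of both genes' means turned without wild-type replicate 3. That call ended without knockout replicate 1 (adjusted p = 0.1) or 3 (0.218), without a filter (0.315), without both end libraries (0.373) and with the milk covariate (0.258). Ribosomal protein genes (18 of 42 above the median, camera adjusted p = 0.911), involution genes (11 of 21, 0.376) and genes of the unfolded protein response (17 of 30, 0.643) were not called. Nor were TGF-beta targets (8 of 14, 0.151), Notch and Hedgehog targets (3 of 8, 0.549) or genes of epithelial-mesenchymal transition (6 of 16, 0.911). Some lists not called with all libraries were called by camera in other settings, and 3 of them were called in both directions. Ribosomal protein genes were called higher without both end libraries (adjusted p = 1.03e-06), without wild-type replicate 1 (0.0429) or knockout replicate 3 (0.0123), and with library quality weights (7.60e-12), but lower without knockout replicate 1 (0.0146). Basal markers were called higher with the milk covariate (2.18e-05) and without knockout replicate 1 (0.0316), but lower without knockout replicate 2 (0.00226) and with library quality weights (0.000698). TGF-beta targets were called higher without wild-type replicate 1 (0.033) or 2 (0.0232), without knockout replicate 1 (0.0018) and with the milk covariate (1.65e-05), but lower with library quality weights (0.0171). Notch and Hedgehog targets were called lower without wild-type replicate 1 (0.0436) and without both end libraries (0.042). Adipocyte genes were called higher without wild-type replicate 2 (0.0307), and muscle and nerve genes without wild-type replicate 2 (0.00932) or knockout replicate 3 (0.00228). Genes of epithelial-mesenchymal transition were called lower with library quality weights (0.0238). Without a filter on low FPKM, genes of T and NK cells (4.50e-05), neutrophils and mast cells (9.98e-07) and erythrocytes (0.00162) were called higher. With an estimated correlation, 0 lists were called under any of these settings.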

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

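The fit without the libraries at both ends of the first component and the fit with milk protein expression as a covariate were chosen after the data were seen. Nmi was lower in the knockout under every setting in which it was tested, with log2 fold changes from -2.69 (pseudocount of 0.1) to -0.59 (pseudocount of 5), and -1.70 to -1.32 with 1 library left out. It was filtered out at an FPKM minimum of 5. Its adjusted p passed the threshold only with library quality weights (-1.68). That setting called 1793 genes higher and 5947 lower and 5 lists each way, but its fit did not converge and gave wild-type replicate 2 and knockout replicate 1 weights of 27.6 and 39.2 against 0.111 to 0.262 for the others, so it compares 1 mouse with 1 mouse in effect. It also gave the other direction for Cyp51 (-0.082), Rel (-0.067), H2-Aa (-0.0046), C1qb (-0.23) and Kit (0.074).

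Genes past the adjusted threshold numbered 0 in each direction under every other setting, except 1 higher (Gm7367, a predicted gene, named after its value was seen) without both end libraries. With 1 library left out, unadjusted calls ranged from 25 (wild-type replicate 1) to 1187 (knockout replicate 2), with 632 for wild-type replicate 3 and 59 for knockout replicate 3. They numbered 7852 with library quality weights, 326 without a filter, 51 at an FPKM minimum of 5 and 78 without both end libraries. The number of lists called by camera, 10 higher and 1 lower, was 0 and 0 with an estimated correlation and with fry. It was 5 and 2 without both end libraries, 9 and 2 with the milk covariate, and 10 and 2 without a filter. With 1 library left out it ran from 8 to 13 higher and from 1 to 3 lower. No other setting moved these numbers by more than 1.5 times. Of 700 fold changes of the other named genes over all settings, 662 kept their direction and stayed short of the threshold, 33 passed it in the same direction and 5 changed direction. The 33 and the 5 all came from the fit with library quality weights, which did not converge. No paired analysis was possible, because the mouse numbers do not show whether mice of both genotypes shared a litter or a day of collection. The cause of these differences was not tested beyond the weights. The absolute depth is unknown, so depth could not be set against the counts of low genes.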

Other observations

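The tests on the first component, on the chromosome 15 genes and on ATF4 targets were chosen after the results were seen; the splits of the libraries were fixed beforehand. Mice differed as widely within a genotype as between genotypes: the log2 differences of a pair of libraries had a mean SD of 0.432 within and 0.418 between. The widest pair was wild-type replicate 1 and knockout replicate 3 (0.741), and the widest pair within a genotype had 0.577. Along the first component, 35 of 35 tested genes of milk lipid and cholesterol synthesis had higher values toward knockout replicate 3 after quantile normalization and 12 of 16 luminal alveolar and progenitor markers had lower ones. Higher values there were also held by 30 of 31 mitochondrial respiratory chain genes, 34 of 39 interferon-stimulated genes and 20 of 27 NF-kB targets. The same held for 23 of 27 dissociation stress genes and 19 of 22 cell cycle genes. Of 20 milk protein genes, 12 had higher values and 5 lower ones. Lower ones were held by 20 of 22 basal markers and 35 of 42 ribosomal protein genes. The share over all tested genes was not computed. The genes that follow were chosen after their values were seen. The fatty acid synthase gene Fasn had 17.6, 28.6 and 108.6 FPKM in wild-type replicates 1, 2 and 3 and 48.6, 26.0 and 363 FPKM in knockout replicates 1, 2 and 3. Thrsp, a regulator of lipid synthesis, had 25.8, 68.6 and 122.7 FPKM in wild type and 150.9, 31.0 and 378 FPKM in the knockout. The phosphate transporter gene Slc34a2 ran from 1.497 FPKM in wild-type replicate 1 to 103.1 FPKM in knockout replicate 3. Krt7 ran the other way, with 215, 75.2 and 37.0 FPKM in wild type and 23.9, 79.7 and 4.23 FPKM in the knockout. Krt8 had 1515, 929 and 647 FPKM in wild type and 596, 983 and 198 FPKM in the knockout, and Anxa1 454, 185 and 151 FPKM in wild type and 162, 220 and 41.9 FPKM in the knockout.

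One pattern to follow up is this axis, of which scaling by the milk transcripts was tested as the whole origin. After quantile normalization the first component still held 60.8% of the variance, against 73.8% as deposited, so scaling accounts for part of it at most. These percentages are of different totals, so they do not give the size of that part. A different share of epithelial cells would move the markers of other cell types alike. The mean change from one end of the axis to the other was taken after quantile normalization. On the log2 scale it was 1.39 (SE 0.25) for macrophage genes and -0.18 (SE 0.10) for endothelial genes. The gap was 1.57 (SE 0.27), for a pair chosen after the results were seen. These SE are over genes, which vary together, and not over mice. Fibroblast (0.11, SE 0.18) and muscle and nerve genes (-0.36, SE 0.35) lay near the endothelial ones. Adipocyte genes (0.31, SE 0.69) varied too widely to be placed. As deposited, the mean of 4 erythrocyte genes also rose, from -0.596 in wild-type replicate 1 to 1.22 in knockout replicate 3. That these lists did not move alike argues against that share as the sole origin, but only between the mice at the ends of the axis. A change in macrophages stays open. A difference between mice in how far secretory activation had gone when the glands were taken is a candidate explanation that stays open; the labels give no hour after birth or litter size, and apart from the share of cells no biological explanation was tested.

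This structure bears on the genotype comparison. With 10 splits of the 6 libraries into 3 and 3 the share of splits can never be under 0.05, so they cannot settle whether chance alone gives the observed counts. The real split gave 0 genes past the adjusted threshold, a number that all 10 splits reach whatever they give, so that count carries no evidence; the highest other split gave 60. At an unadjusted p under 0.05 the real split gave 130 genes, 5 of the 10 splits gave as many, and the highest other gave 3690. For lists called by camera the real split gave 11, 5 of the 10 splits gave as many, and the highest other gave 14. The split with 60 and 3690 genes set wild-type replicates 1 and 2 and knockout replicate 2 against the rest. It divides the libraries by the sign of their first component score. It thus restates that component, from the same values, and is no further evidence for a structure other than genotype.

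A list of 27 ATF4 targets and serine synthesis genes, written after Psat1 and other members had been seen, had a median log2 fold change of -0.44 as deposited, -0.17 after trimmed-mean rescaling and -0.26 after quantile normalization, with 21, 19 and 20 genes below the median of all genes. Among the members with non-overlapping groups, picked after they were seen, Psph had 2.77, 1.89 and 1.58 FPKM in wild type and 1.03, 1.24 and 1.16 FPKM in the knockout, and Sesn2 11.045, 11.6 and 8.15 FPKM and 6.77, 6.93 and 6.03 FPKM. Scaling by milk transcripts may account for part of the fold change: fry gave p = 0.0664 as deposited and 0.228 after trimmed-mean rescaling, and an exact permutation test of the list mean 0.1, the smallest possible, and 0.3. It leaves the distance of the list mean from the median of all genes nearly as it is (-0.25 as deposited, -0.22 and -0.24 after the rescalings), for which spread between mice in correlated genes stays open (camera with an estimated correlation, p = 0.197, 0.165 and 0.114). Without the libraries at both ends of the first component that p was 0.0412, but as the list was chosen for the pattern, no p on it can establish the pattern.

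Cbx6, Cbx7 and Apobec3 lie side by side on chromosome 15 of GRCm38, at 79823896 to 79834688, 79915807 to 79971119 and 79891659 to 79915906, and were lower in all knockout libraries as deposited; the annotated ends of Cbx7 and Apobec3 overlap, and reads there cannot be told apart without strand. Apobec3, a cytidine deaminase that restricts retroviruses, had 38.9, 31.0 and 30.03 FPKM in wild type and 19.1, 17.9 and 23.7 FPKM in the knockout; after trimmed-mean rescaling the log2 fold changes were smaller, -0.43 against -0.69 for Apobec3, whose groups then overlapped, -0.71 against -0.94 for Cbx6 and -0.58 against -0.80 for Cbx7. A common shift of the wider region is argued against. The 60 other tested genes within 2 Mb had a median of -0.00491 relative to that of all genes. The SE of their mean, taken over genes, was 0.0282. Of these 60 genes, 30 lay below the median of all genes. Non-overlapping groups were found for 5 of the 60, a larger share than the 4.61% of all genes tested. A median cannot exclude changes that go both ways. Chance placement stays open: for the 59 mapped genes lower in all knockout libraries at an unadjusted p under 0.05, these 3 among them, random sets held as many pairs within 250000 bases with a one-sided permutation p of 0.086. For all 362 mapped genes lower in all knockout libraries there were 67 pairs against a mean of 38.9 (permutation p = 0.000600), but such draws ignore that neighbouring genes may vary together, and a chromosome segment from another strain could not be tested without genotypes.

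Around Nmi itself, the 27 other tested genes within 10 Mb included 0 with non-overlapping groups. As only 4.61% of all genes tested had such groups, few would be expected among 27 genes, and this count says little about the region.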
